A study of Prunus persica with 32 samples.

How the data were processed

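RNA was taken from the upper and lower side of internodes 1 and 2 of horizontal lateral branches of greenhouse-grown, untreated standard and weeping peach trees. Per the labels' protocols, total RNA was extracted with a column kit and cleaned with a DNA digestion step, strand-specific mRNA libraries were pooled, and single-end reads of 50 bases were made on an Illumina HiSeq instrument. Each library's deposited table lists 26873 genes, 62 of them on scaffolds and the rest on 8 chromosomes. Per the file headers, the deposited counts are total and unique gene reads, that is, all reads assigned to a gene and those that mapped to 1 place. The authors also gave TPM, which sums to 1000000 in each file, and RPKM, which equals the expression value column in all 32 files, per the file headers; TPM and RPKM were used only to check the files. The aligner, genome build, annotation and counting settings are not given in the sources used here. Coordinates are those of the files.

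How reads were counted limits some values. The exon length equals the gene length in all 32 files and 0 reads were listed across exon junctions, so introns may count toward a gene's span. Whether counting used the strand is not given in the sources used here, so for the 2746 genes (10.2%) that overlap another, 2296 of them on the opposite strand, reads of the partners cannot be separated. Of each library's reads 95.15% to 96.52% were unique, and genes with a low unique share are uncertain because near-identical copies can trade reads. Depth ranged from 16719437 to 31404417 gene reads, so that 3 reads, the limit allowed by a count of 0, correspond to 0.099 to 0.167 CPM. Poisson intervals are at 95% and cover counting error only.

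Groups were taken from the labels, which name the tree and branch of every library. Replicates 1 to 4 are branches, 2 from each of 2 trees per genotype. Library numbers ran in sets by internode and side, with both genotypes within a set. Whether they follow the order of handling is not given in the sources used here. An effect of that order could not be told apart from side or internode. Because the pieces of a branch come from 1 shoot, the branch was kept as a block, a choice fixed with the tests, named-gene rule and most alternatives before the data were examined. The deviations of upper and lower pieces of a branch from their group means correlated at 0.419 to 0.876 in internode 1 and 0.578 to 0.973 in internode 2, and each branch correlated best with itself in 8 of 8 cases. Between internodes the correlations ran from -0.29 to 0.767, with 7 of 8 best with their own branch. No pair of libraries in a group agreed within sampling noise, the smallest chi-square per degree of freedom being 24.3.

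Counts were tested with edgeR 4.0.16 (robust quasi-likelihood F test, TMM normalization, filterByExpr with a minimum count of 10) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg with genes called at 0.05. The upper and lower sides were compared within each genotype in 1 fit of 16 libraries per internode, together with the difference of these contrasts. Genotypes were compared on counts summed per tree, 2 against 2, and internodes on counts summed over the sides of each branch. CPM (reads per 1000000) use TMM-scaled library sizes, except levels per tree, which are summed reads over summed gene reads without that scaling. Fold ratios of genes with few reads were taken from summed reads per group over depth. The SE of a log2 fold change from edgeR is its size over the square root of F, and not a spread of branch values. Agreement between genotypes is a correlation across genes, with a jackknife over branches for its error.

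The scripts were tested on simulated data with known changes. These were set in genes with an average log2 CPM over 1. Counts were drawn from the negative binomial at the dispersions estimated per gene from the real data. The shares found therefore hold for such genes and counts only. For the side test in weeping internode 2 (19610 genes), 91% of genes changed by 1 log2 unit and 99% of those changed by 2 were found, with 13 false calls. In internode 1 (20086 genes) the shares were 66% and 93% with 2 false calls. For the genotype test (22039 genes) they were 5% and 72% with 9 false calls, and for the internode test in weeping (20772 genes) 67% and 89% with 6 false calls. The test of how close called genes lie to each other found 20 of 20 simulated lists with 2 planted blocks of 10 genes, but 4 of 20 with 1 block, and 1 of 20 random lists passed in each setting; the setting with 2 blocks was added after the low yield with 1 had been seen.

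The named-gene rule took, for each comparison, the genes with the largest change among those that passed, with an average log2 CPM of at least 1 and the same direction in every branch or tree (no such condition for differences of contrasts), and those with the smallest p where fewer than 5 passed. Of the 26873 identifiers 0 matched the reference table of 26412 genes, so that no names or descriptions were used and at most 2 genes per direction were named. For the same reason the condition on the description of the WEEP locus could not be checked, and the 28 gene lists planned on auxin, gravitropism, cell wall and tissue markers could not be tested. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter and a stricter filter, unique reads, no block, each genotype alone, each branch or tree left out, and for genotype limma 3.58.1 with the tree as a random block. The score along the internode axis, its use as a covariate, the mean side contrast over genotypes and the difference of internode contrasts were added after the data were seen. The score of a library is its projection on the mean internode change of the other branches over genes with an average log2 CPM of at least 3. Figures were drawn with matplotlib 3.10.9.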

Results

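Gene expression was measured by RNA sequencing in potted peach trees (Prunus persica) of standard architecture, whose shoots grow upward, and of weeping architecture, whose shoots arch downward. Tissue was cut from the upper and the lower side of horizontal lateral branches at internodes 1 and 2. The question behind the sampling was how WEEP, a gene whose loss gives peach trees their weeping form, takes part in the auxin gradient that arises across a shoot in response to gravity. The 32 libraries fell into 8 groups of 4, 1 for each combination of genotype, internode and side. Each group held 4 branches, taken from 2 trees per genotype, and the 4 pieces of a branch came from the same shoot. P-values for side and internode therefore measure the spread between branches of 2 trees per genotype, and those for genotype the spread between trees. Tests of whether a contrast differs between genotypes also take branches as replicates, and so treat branches of a tree as independent. Gene reads per library ranged from 16719437 to 31404417, with a mean of 26367000, and reads were counted for 21762 to 22782 of 26873 genes per library.

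The WEEP locus gave almost no reads in weeping trees. Whether its reads fail to map in weeping trees was left open, as for the other genes called lower there. Prupe.3G200700, the gene known from work on weeping peach as WEEP, lies on the minus strand of chromosome 3 at 20944039 to 20946994, a span of 2956 bp. It gave 30878 reads over the 16 standard libraries and 81 over the 16 weeping libraries, with 1148 to 3122 reads in each standard library and 0 to 15 in each weeping library. Relative to depth the standard level was 380 times the weeping level (95% Poisson interval 305 to 478, which covers counting error only), and the 81 reads had an exact Poisson interval of 64.3 to 101. Per tree the level was 73.7 ± 17.3 CPM in standard and 0.193 ± 0.0529 CPM in weeping trees (SD, n = 2 trees each). The log2 fold change was -8.54 (SE 0.35; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0312). Without 1 of the 4 trees it was -8.84 to -8.29, with edgeR adjusted p of 0.131 to 0.238. In standard branches the locus was read at similar levels on both sides of each internode. In internode 1 it stood at 58 ± 7.38 CPM on the upper and 61 ± 10.2 CPM on the lower side, and in internode 2 at 84.5 ± 25.3 and 90.1 ± 27.3 CPM (SD, n = 4 branches). The upper-to-lower log2 change was -0.07 (SE 0.24, edgeR adjusted p = 0.977) in internode 1 and -0.10 (SE 0.06, edgeR adjusted p = 0.511) in internode 2, and the change from internode 1 to internode 2 was 0.51 (SE 0.24, edgeR adjusted p = 0.153). The plot of CPM per library shows the gap between the genotypes. That the gene carries the domain for which WEEP is known was not checked, because no gene description was used here.

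**Figure D1:**
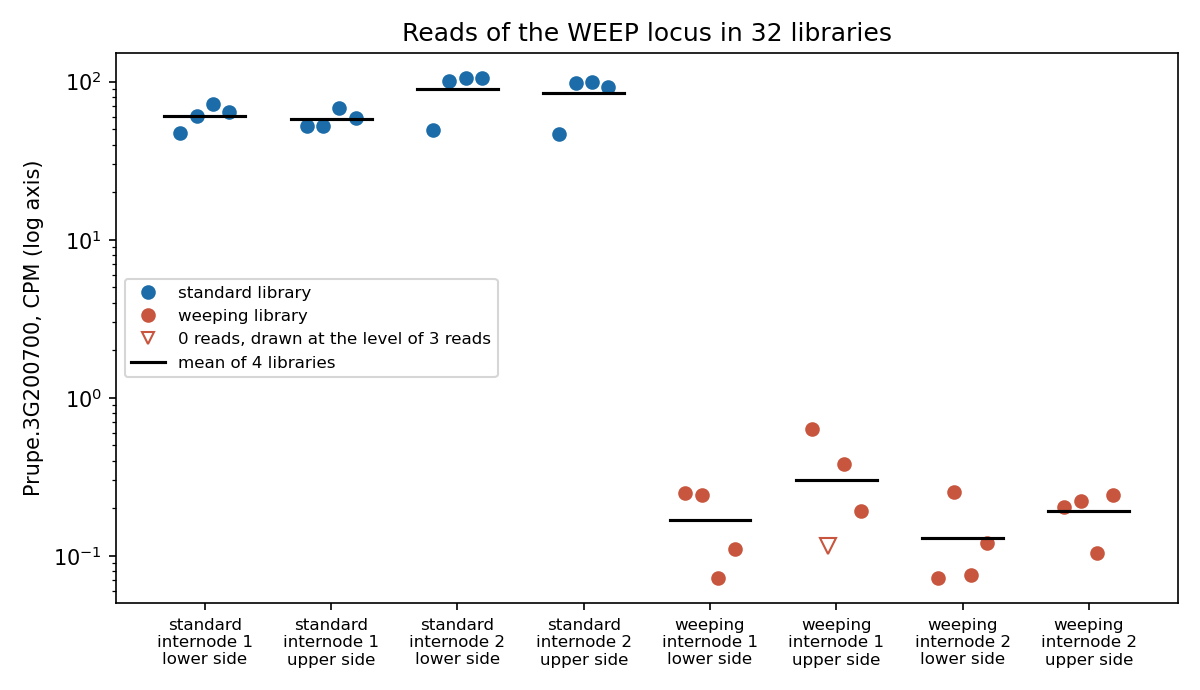
CPM of Prupe.3G200700 in each of the 32 libraries on a log axis, by genotype, internode and side; points are libraries, black lines are means of 4, and the open triangle is the 1 weeping library with 0 reads, drawn at the level of 3 reads. The standard groups average 58 to 90.1 CPM and the weeping groups 0.13 to 0.304 CPM.

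At the level of trees edgeR called 35 of 22039 genes between the genotypes, the WEEP locus among them, 9 higher and 26 lower in weeping trees. Each changed by at least 2.51 on the log2 scale. In simulation this test of 2 trees against 2 found 5% of changes of 1 log2 unit and 72% of changes of 2. The simulated counts had no spread beyond the estimated dispersions, so these shares may be too high for real trees. All 9 higher genes and 24 of the 26 lower genes differed more than 8-fold. Prupe.3G055500 (chromosome 3, 3930876 to 3935501) stood at 47.6 ± 3.11 CPM in weeping and 0.0307 ± 0.00103 CPM in standard trees, a ratio of 1550 (Poisson interval 905 to 2910). Prupe.4G229000 (chromosome 4, 14650114 to 14652286) was 1210 times higher in weeping (786 to 1990), with 35.3% of its reads mapped uniquely. It was uneven there, from 0.0768 to 150 CPM in the weeping libraries against 0 to 0.373 CPM in the standard libraries. Prupe.6G175900 (chromosome 6, 18013547 to 18016450) stood at 11.8 ± 0.341 CPM in standard trees and had 3 reads in all weeping libraries, a ratio of 1650 (565 to 8020). Prupe.3G110500 (chromosome 3, 9077469 to 9082341) was 830 times lower in weeping (355 to 2560). The files do not pair these identifiers with names.

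Chromosome 8 held 12 of the 35 genes that differed between genotypes, all lower in weeping, and 10 of these fell between 1913072 and 3048025, a stretch with 93 tested genes, where log2 fold changes ran from -8.80 to -3.23. The other 2 on chromosome 8 lay side by side at 11258287 to 11265989. Chromosome 3 held 10, 4 higher and 6 lower in weeping, the WEEP locus among them. Within 1 Mb of the WEEP locus 268 other genes were tested and edgeR called 0, with 16 at an unadjusted p under 0.05 and 6 called by DESeq2. The nearest other called gene was 4298.6 kb away. The map of called genes shows these positions.

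**Figure D2:**
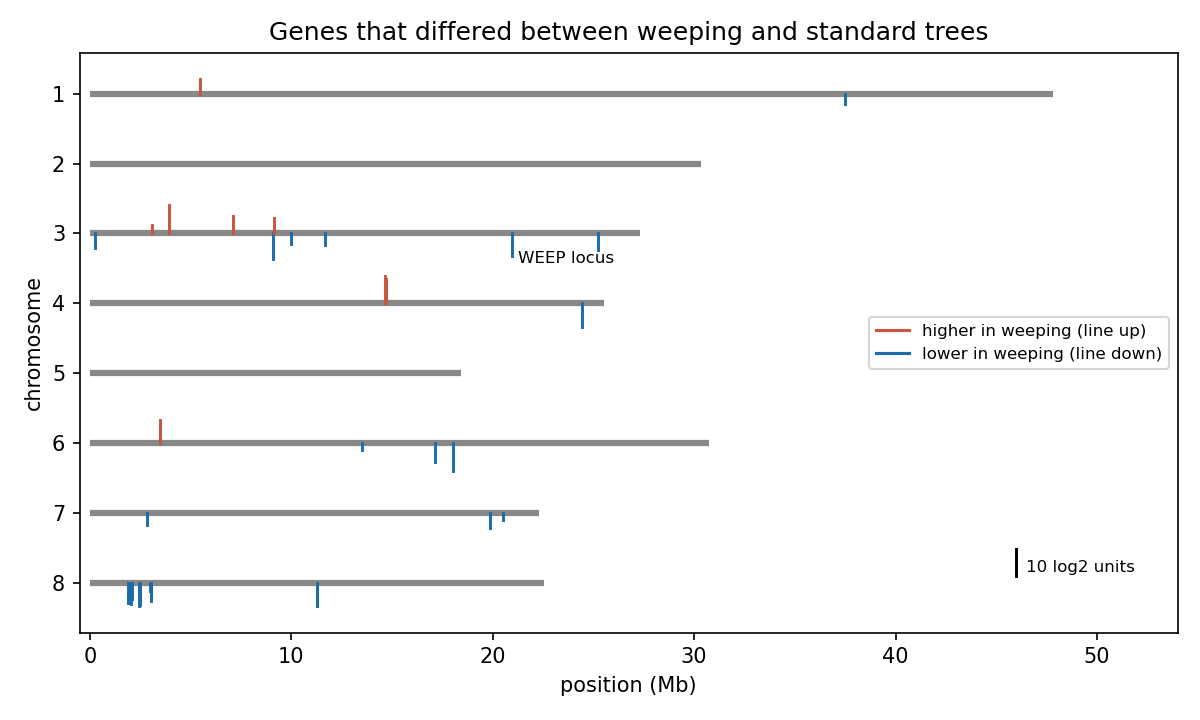
Positions (Mb) of the 35 genes that edgeR called between weeping and standard trees along the 8 chromosomes; each line marks 1 gene, its height is the log2 fold change to the scale bar, and grey bars end at the last gene. Of the 12 genes on chromosome 8, 10 lie between 1913072 and 3048025, and the WEEP locus on chromosome 3 has no neighbour called by edgeR within 1 Mb.

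The genotype test used edgeR's quasi-likelihood method on counts summed per tree, 2 against 2, with Benjamini-Hochberg adjustment. Without any 1 of the 4 trees edgeR called 0 genes, with 735 to 1407 at an unadjusted p under 0.05 against 970 with all trees, and DESeq2 called 434 with all trees. With branches as replicates, which treats branches of a tree as independent, 292 genes were called. Of the 35 genes, 5 had under 50% of their reads mapped uniquely. On uniquely mapped reads alone edgeR called 28 genes.

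Expression changed most along the shoot. In standard branches 4843 of 20772 genes differed between internodes, 2284 higher and 2559 lower in internode 2, and 2040 of them more than 2-fold. In weeping branches 2577 differed, 1040 higher and 1537 lower in internode 2, with 1105 over 2-fold. Prupe.8G128900 (chromosome 8, 15240821 to 15244527) was read at 64.7 ± 100 CPM in standard internode 1 (SD, n = 4) and had 0 reads in standard internode 2, at least 4990-fold higher in internode 1 against a floor of 3 reads over the group. Replicate 1 held 82% of these reads, and without it the limit was 867-fold. Prupe.1G096800 (chromosome 1, 7691982 to 7696328) stood at 155 ± 253 CPM in weeping internode 1 and at 0 reads in internode 2, at least 11100-fold higher, with 39.2% of its reads mapped uniquely. Replicate 3 held 86% of its internode 1 reads, and without it the limit was 1500-fold. In the other direction Prupe.1G458900 (chromosome 1, 38428096 to 38429891) was 50.9 times higher in weeping internode 2 (40.7 to 64.5), and Prupe.6G166000 (chromosome 6, 16720210 to 16721127) 10.7 times higher there (10.3 to 11.1), with levels of 155 ± 150 against 14.6 ± 25.5 CPM. These Poisson intervals leave out the spread between branches: without replicate 1, which held 66.3% and 59.5% of their internode 2 reads, the ratios were 36.9 and 41.2. Folds without a branch were added after the data were seen. For Prupe.6G166000 the edgeR adjusted p of 0.0302 rose to 0.0658 without weeping replicate 1, 0.0988 without replicate 2, 0.13 without replicate 4 and 0.0534 without standard replicate 3. Without the branch as a block it was 0.35, against 0.108 for Prupe.1G458900 in weeping and 0.0713 for Prupe.8G128900 in standard (edgeR).

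The internode difference ran the same way in both genotypes. Library numbers also parted the internodes in both genotypes, so an effect of library order cannot be told apart from it. Across genes, which are not independent replicates, the log2 changes of the genotypes correlated with Pearson's r = 0.89 and Spearman's rho = 0.789. Of the genes called in standard 98.3% had the same sign in weeping, and 99.3% of those called in weeping had the same sign in standard. Higher in internode 2 in both were 888 genes, where independent lists of these sizes would share 114.4, and lower in both were 1406, where they would share 189.4; 0 genes were called in opposite directions. The difference of the internode change between genotypes was called by edgeR for 0 genes, with 847 at an unadjusted p under 0.05 and 54 called by DESeq2. Counts were tested with edgeR on sums over the sides of each branch, with the branch as a block. Without the block 1445 genes were called in standard and 411 in weeping; leaving out 1 branch gave 2571 to 5293 in standard and 896 to 3208 in weeping.

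Libraries also differed in how far they lay along the internode axis, given as a score over 14050 genes with 1 unit for the mean step from internode 1 to internode 2. Internode 1 groups averaged -0.58 to -0.23 and internode 2 groups 0.44 to 0.48. The internode 2 pieces of standard replicate 1 (both at -0.43) and of weeping replicate 3 (-0.35 lower, -0.28 upper) scored near internode 1. In internode 1 the sides of a branch differed in score by -0.28 to 0.55, and in internode 2 by -0.11 to 0.09. The upper-minus-lower score in internode 1 averaged 0.30 ± 0.35 in weeping and -0.07 ± 0.22 in standard branches (SD, n = 4 each; exact two-sided permutation p = 0.114, 0.228 after Benjamini-Hochberg adjustment over 2 tests). In internode 2 the difference between genotypes was 0 (exact permutation p = 0.971, adjusted 0.971). The plot of scores by branch shows these values.

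**Figure D3:**
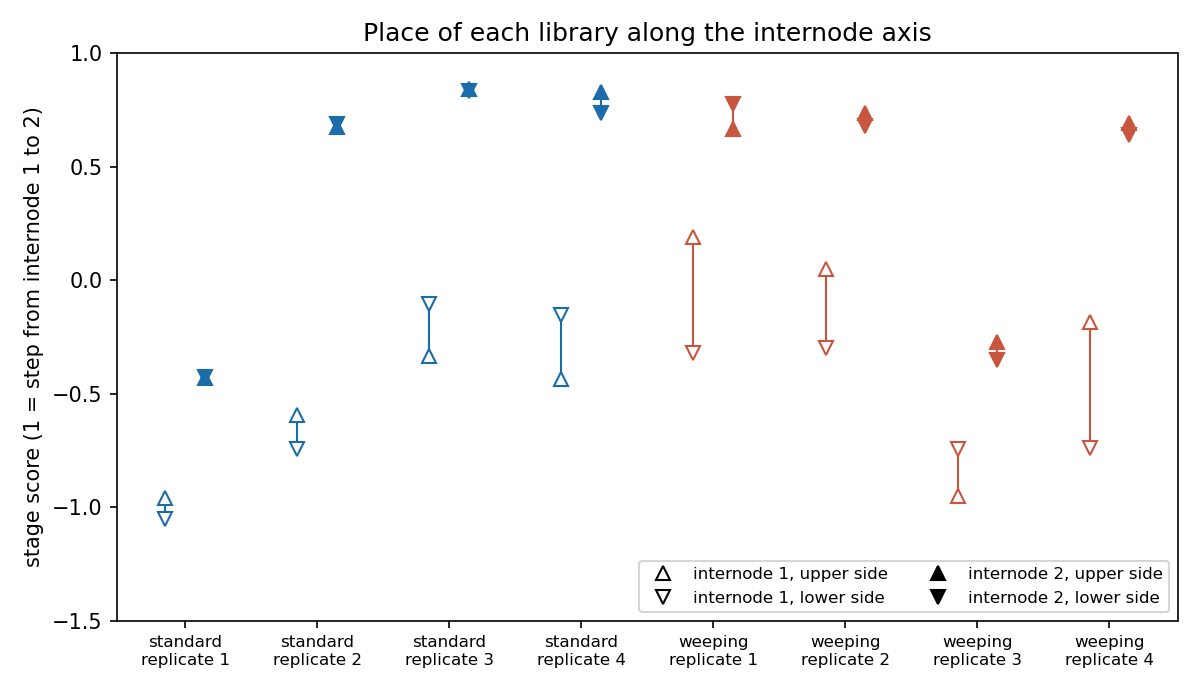
Score of each library along the internode axis (1 unit is the mean step from internode 1 to internode 2) for the 8 branches; open symbols are internode 1, filled symbols internode 2, upward triangles the upper and downward triangles the lower side, and lines join the sides of an internode. Sides of internode 2 lie within 0.11 of each other, and those of internode 1 up to 0.55 apart.

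In internode 2 of weeping branches the upper and lower sides differed in 1176 of 19610 genes, 890 higher and 286 lower on the upper side, and 219 of them over 2-fold. Prupe.6G214400 (chromosome 6, 22236784 to 22239254) rose from 0.585 ± 0.854 CPM on the lower to 45 ± 57 CPM on the upper side (SD, n = 4), higher in 4 of 4 branches. Its log2 fold change was 6.27 (SE 0.47, edgeR adjusted p = 0.00242). Its differences in log2(CPM + 0.5) per branch ran from 1.18 to 6.01, a wider spread than this SE conveys. Prupe.1G271700 (chromosome 1, 27854746 to 27856083) stood at 86.3 ± 28.5 CPM on the upper and 10.4 ± 18 CPM on the lower side, with a log2 fold change of 4.37 (SE 0.94, edgeR adjusted p = 0.0327). Lower on the upper side were Prupe.6G099100 (chromosome 6, 6896780 to 6897667), at 2.26 ± 2.79 against 29.4 ± 30.3 CPM and a log2 fold change of -3.56 (SE 0.67, edgeR adjusted p = 0.0211), and nearby Prupe.6G098900 (6884864 to 6885760), at 3.58 ± 4.27 against 29.2 ± 29.6 CPM and -2.92 (SE 0.43, edgeR adjusted p = 0.0117).

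Of these 4 genes, the pair on chromosome 6 had 34% and 33.8% of their reads mapped uniquely. Without the block, adjusted p was 0.0926 for Prupe.6G214400 and 0.857 or more for the others. Adjusted p of Prupe.6G099100 was 0.0877, 0.108 and 0.0621 without weeping replicates 1, 2 and 4, that of Prupe.6G098900 was 0.0583 and 0.0667 without replicates 1 and 2, and that of Prupe.1G271700 was 0.136, 0.123 and 0.0683 without weeping replicates 1, 2 and 4 and 0.0586, 0.0622 and 0.0591 without standard replicates 1, 3 and 4 (edgeR, Benjamini-Hochberg).

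In internode 2 of standard branches edgeR called 0 of 19610 genes between the sides, with 2829 (14.4%) at an unadjusted p under 0.05, a smallest adjusted p of 0.0528 and 773 genes called by DESeq2. The genes nearest to the threshold ran the same way in 4 of 4 branches. Prupe.8G100600 (chromosome 8, 13177522 to 13182068) stood at 61.8 ± 19.6 CPM on the upper and 44.6 ± 16.7 CPM on the lower side, a log2 difference of 0.48 (SE 0.05), and Prupe.2G044200 (chromosome 2, 4938188 to 4941270) at 81.2 ± 8.88 and 49.7 ± 6.34 CPM, 0.70 (SE 0.08). Prupe.2G005200 (chromosome 2, 508224 to 513226) differed by -0.70 (SE 0.09) and Prupe.5G202000 (chromosome 5, 16284204 to 16285809) by -0.87 (SE 0.13). The 0 depends on the libraries in the fit: with the standard libraries alone 626 genes were called in standard, with the weeping libraries alone 402 in weeping, and without a filter on low counts 97 in standard. Without weeping replicate 3, whose internode 2 scored near internode 1, edgeR called 237 genes in standard and 1904 in weeping, and without weeping replicate 4 it called 30 and 478. The weeping count was 185 without weeping replicate 1, 214 without replicate 2 and 704 without standard replicate 3. Without the branch as a block it was 72.

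The side differences of internode 2 were partly shared between genotypes. Across genes the log2 changes correlated with r = 0.219 (jackknife SE over branches 0.113) and rho = 0.382. The same sign was found in 65.7%, where chance gives 0 for a correlation and 50% for signs. An effect of library order shared by both genotypes would also raise these values and cannot be told apart from side. Among genes with an average log2 CPM of at least 3, r was 0.379, and without a filter on low counts it was 0.075. It was 0.077 without standard replicate 2, the lowest without 1 branch. Of the 1176 genes called in weeping, 1007 (85.6%) had the same sign in standard, 789 of these 1007 with an unadjusted p under 0.05 there. The median ratio of the standard to the weeping change over the 1176 was 0.64. Same and opposite signs went with size: of 323 genes up to 0.5 log2 units higher in weeping 306 had the same sign in standard. Of 56 genes over 2 log2 units higher, 20 had the same and 36 the opposite sign. Of these 36, 16 lay in 1 run on chromosome 8 and 20 elsewhere, as many as had the same sign. The plot of both changes shows the genes along the diagonal and those at the upper left. Limits on size were chosen after the plot had been seen.

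**Figure D4:**
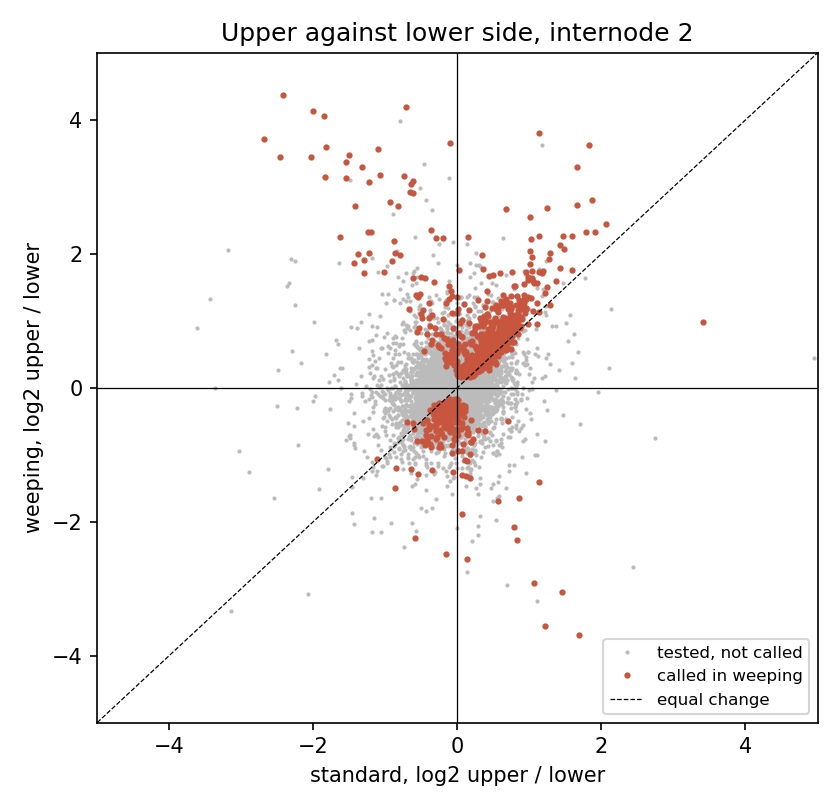
Log2 fold change of the upper against the lower side in internode 2, standard on the x axis and weeping on the y axis, for 19605 of 19610 tested genes (5 lie outside the axes); red points are the genes called in weeping and the dashed line marks equal change. Of the 1176 called genes 1007 have the same sign in both genotypes. Of the 56 that are over 2 log2 units higher in weeping, 36 are lower in standard, 16 of them in 1 run on chromosome 8.

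The test of the difference itself called 9 genes in internode 2, 7 with a higher and 2 with a lower upper-to-lower change in weeping. Prupe.6G214400 again led, with 0.273 ± 0.185 CPM on the upper and 2.08 ± 1.68 CPM on the lower side in standard branches, the opposite order to weeping, and a difference of 9.09 log2 units (SE 0.71, edgeR adjusted p = 0.0139). Prupe.6G166000 stood at 284 ± 264 CPM on the upper and 24.9 ± 39 CPM on the lower side in weeping, and at 27.7 ± 33.9 and 84.7 ± 85.1 CPM in standard, a difference of 5.91 (SE 0.63, edgeR adjusted p = 0.035). Prupe.7G048300 (chromosome 7, 8538580 to 8542476) and Prupe.6G101800 (chromosome 6, 7075398 to 7076899) differed by -2.26 (SE 0.27, edgeR adjusted p = 0.0437) and -1.96 (SE 0.24, edgeR adjusted p = 0.0442). Prupe.7G048300 was read at 70.3 to 203 CPM in the internode 2 pieces of standard replicate 1 and weeping replicate 3 and at no more than 3.94 CPM in the others. Each of the 4 genes lost its call without any 1 of at least 5 of the 8 branches, with edgeR adjusted p up to 0.328. The count of 9 was 0 without the block, 4 with a stricter filter on low counts, 173 with DESeq2, and 0 to 198 without 1 branch, with 198 without weeping replicate 3.

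In internode 1 edgeR called 0 of 20086 genes between the sides in standard branches, with 1082 (5.4%) at an unadjusted p under 0.05 and 26 called by DESeq2. In weeping branches it called 0, with 2178 (10.8%) at an unadjusted p under 0.05 and 522 called by DESeq2. Nearest to the threshold in weeping was Prupe.2G324700 (chromosome 2, 30032812 to 30034737, overlapping a gene on the other strand), at 13.6 ± 6.77 CPM on the upper and 2.39 ± 1.27 CPM on the lower side, higher in 4 of 4 branches with a log2 difference of 2.50 (SE 0.27, edgeR adjusted p = 0.0571). Prupe.1G041600 (chromosome 1, 2976884 to 2978561) differed by 1.20 (SE 0.14) and Prupe.5G065300 (chromosome 5, 7935050 to 7936520) by -0.87 (SE 0.10), at the same adjusted p. In standard Prupe.1G585400 (chromosome 1, 47530289 to 47533780) differed by 1.22 (SE 0.19) and Prupe.4G088000 (chromosome 4, 4316520 to 4319726) by 0.51 (SE 0.08), each with an edgeR adjusted p of 0.887. Without weeping replicate 3 edgeR called 684 genes in weeping, and without standard replicate 1 it called 9.

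Across genes the side changes of internode 1 did not correlate between genotypes beyond the error, with r = -0.195 (jackknife SE 0.212; -0.273 to -0.035 without 1 branch), rho = -0.094 and 48.3% of genes with the same sign. With the score along the internode axis as a covariate, a setting added after the data were seen, r was -0.536. That fit had 1 slope of the score for both genotypes, whose mean upper-minus-lower scores had opposite signs (0.30 in weeping, -0.07 in standard). Error in the slope pushes the 2 side changes apart, so chance need not give 0 for this r. Without the covariate the difference between genotypes was called for 9 genes, 3 with a higher and 6 with a lower upper-to-lower change in weeping. Prupe.1G306700 (chromosome 1, 29980212 to 29983073) stood at 76.9 ± 31.8 CPM on the upper and 39.2 ± 13 CPM on the lower side in weeping, and at 23 ± 8.5 and 36.6 ± 16.1 CPM in standard, a difference of 1.60 (SE 0.18). Prupe.6G132300 (chromosome 6, 10434833 to 10437219) differed by 1.80 (SE 0.21), Prupe.3G103200 (chromosome 3, 8097111 to 8098590) by -2.68 (SE 0.31) and Prupe.4G041800 (chromosome 4, 1972647 to 1974447) by -2.36 (SE 0.25), all 4 with an edgeR adjusted p of 0.0446. These genes also changed along the shoot, by 1.94, 2.37, -3.82 and -10.11 log2 units from internode 1 to internode 2 in standard, so their differences have the sign that the higher score of the upper side in weeping would give. With the score as a covariate they were 1.41, 1.51, -2.48 and -2.25, with edgeR adjusted p of 0.0198 to 0.0234. Each lost its call without any 1 of at least 6 of the 8 branches, with edgeR adjusted p up to 0.232. The count of 9 was 0 without the block, 561 with DESeq2, 0 to 236 without 1 branch (236 without weeping replicate 3), and 1128 with the score as a covariate.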

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

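Chosen only after the result was seen were the tests of stage and of a common direction for internode 1, the test of shared signs for internode 2, and the score along the internode axis with its use as a covariate; the other tests of this part were fixed before their values were seen.

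In internode 1 the side differences of single branches followed the internode axis, in both directions: across genes the correlation of a branch's upper-minus-lower difference with the internode change of the other branches was over 0.3 in size in 5 of 8 branches (-0.521 to 0.687), against 0 of 8 in internode 2. Depth does not account for this, since the sign of the correlation matched that of the depth difference in 4 of 8 branches. Nor does an effect of the side common to the standard branches, as 2 of 4 were positive and 2 negative. All 4 were beyond 0.1 in size. The standard signs followed the tree, at 0.126 and 0.178 in tree 1 and -0.521 and -0.496 in tree 3. In weeping a common effect of the side stays open, as 3 of 4 were positive and replicate 3 alone was negative. Both branches of weeping tree 1 were positive, and those of tree 3 had opposite signs. A candidate explanation is that the pieces cut from the sides of internode 1 differed in developmental stage, by branch or by tree. With 2 trees per genotype these cannot be told apart. With the stage score as a covariate the difference between genotypes was called for 1128 genes, not 9. That score is drawn from the expression of the same libraries, so this rise is no independent evidence of stage. Whether stage across the shoot differs by genotype stays open, as 4 against 4 branches, taken as independent of their trees, gave an exact permutation p of 0.114.

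In internode 2 edgeR called 1176 genes between the sides in weeping and 0 in standard branches (2829 at an unadjusted p under 0.05, 773 by DESeq2). The counts do not show a difference by themselves: 85.6% of the weeping calls had the same sign in standard, between the 90% that a shared asymmetry was set to need and the 60% set to exclude it. A larger asymmetry in weeping may contribute, since the median ratio of the weeping to the standard change was 0.979 over the genes with the smallest p in standard and that of the standard to the weeping change 0.64 over those called in weeping, a gap of 0.339 (0.191 to 0.625 without 1 branch). Each genotype fitted alone gave 626 calls in standard and 402 in weeping, the opposite order. These counts come from fits with separate spreads and do not measure the size of the asymmetry. That 1 branch decides the count cannot be told apart from the rest, as the lowest count without 1 branch was 185, without weeping replicate 1, between the limits set for either reading, and 704, 478 and 214 without standard replicate 3 and weeping replicates 4 and 2, while weeping replicate 3 held it down (1904 without it).

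Whether the libraries were grouped by chance was tested on other splits. For sides and internodes there are 8 splits that part all 4 pairs, too few for a share under 0.05. The real count and the highest of the others were 0 and 0 for the sides of standard internode 1, 0 and 7 in weeping internode 1, and 0 and 0 in standard internode 2, so that 8 of 8 splits called as many. They were 1176 and 8 for weeping internode 2, 4843 and 0 for internodes in standard and 2577 and 1 in weeping, with 1 of 8 splits as high. Among 24 splits that part 2 pairs the highest count was 279 for weeping internode 2 and at most 10 for the others. The difference between genotypes was 9 in internode 1, with a highest other of 0, and 9 in internode 2, with a highest other of 8, with 1 of 35 splits of the 8 branches as high in each. These splits treat branches of a tree as independent, and the 4 trees allow only 3 splits of 2 against 2, too few for a share under 0.05. Without the block both counts were 0.

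Single libraries stood far from the others of their group in 18 of 96 checks of 1 measure in 1 group of 4. Independent checks would give 4.8 by chance. These were not independent, as sides of a branch went together and many measures were CPM of genes named for their changes. The lower side of standard internode 1, replicate 4, had 16719437 gene reads (others 25462691 to 26970782) and 92.51% of its mapped reads in genes (others 97.12% to 97.19%). Standard internode 2, replicate 1, had a score along the internode axis of -0.43 on each side and low CPM of Prupe.3G200700, 49.2 on the lower side (others 101 to 106) and 46.7 on the upper (93.1 to 99.4). Weeping internode 2, replicate 3, scored -0.35 on the lower and -0.28 on the upper side. In both branches Prupe.7G048300 was high, at 130 and 203 CPM on the lower and upper side of standard replicate 1 and 200 and 70.3 CPM in weeping replicate 3. Prupe.1G271700 stood at 37.4 CPM on the lower side of weeping replicate 3 in internode 2 (others 0.242 to 2.39), and Prupe.4G147200 at 58.8 CPM on its upper side in internode 1 (39.3 to 41.4). On the upper side of weeping internode 2, replicate 2, Prupe.6G099100 stood at 6.43 CPM (others 0.616 to 1.02) and Prupe.6G098900 at 9.98 CPM (1.26 to 1.72). Prupe.6G166000 was at 83.2 CPM on the lower side of weeping internode 2, replicate 1 (0.716 to 10.1), and Prupe.4G041800 at 8.88 CPM on the upper side of standard internode 1, replicate 1 (34.7 to 38.8). The side contrast differed between genotypes by the test of the difference, in 9 genes of each internode.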

How the results depend on the processing

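The score along the internode axis as a covariate and the mean side contrast were chosen only after the result was seen; the other settings of this part were planned. Where a count moved, the cause was not tested, apart from fewer trees or branches. No direction reversed. The scaling by DESeq2's size factors and the unique reads kept every count of called genes within 1.5 times. DESeq2 called more genes: 26 and 522 between sides in internode 1 of standard and weeping, 773 in standard internode 2, 561 and 173 for the differences of the contrast in internodes 1 and 2, 434 for genotype and 4377 for internodes in weeping. Without a filter on low counts 97 genes were called in standard internode 2, and with the stricter filter the difference in internode 2 had 4. Without the branch as a block the counts fell to 72 for weeping internode 2, 0 and 0 for the differences, 1445 for internodes in standard, 411 in weeping, and 286 for the mean side contrast of internode 2. Each genotype alone gave 2 for weeping internode 1, 626 and 402 for standard and weeping internode 2, and 3148 and 1408 for internodes in standard and weeping.

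Leaving out 1 branch gave 0 to 684 genes for the sides of weeping internode 1, 0 to 237 for standard internode 2, 185 to 1904 for weeping internode 2, 0 to 236 and 0 to 198 for the differences, 2571 to 5293 for internodes in standard and 896 to 3208 in weeping; for standard internode 1 it stayed at 0. The highest values for weeping internode 1, both genotypes in internode 2 and both differences came without weeping replicate 3. Leaving out any tree gave 0 for genotype, a fit in which the lone tree is assumed to vary like the other genotype. Branches as replicates gave 292, with lower or higher library numbers as a covariate 187, with the tree as a random block in limma-voom 213 (consensus correlation 0.316), and single positions 3 (internode 1 upper), 1 (internode 1 lower), 0 (internode 2 upper) and 10 (internode 2 lower). The correlation of side changes between genotypes was 0.379 in internode 2 for genes with an average log2 CPM of at least 3. It was 0.075 without a filter and 0.356 with the stricter filter (0.077 to 0.219 without 1 branch). In internode 1 it was -0.536 with the stage covariate, where error in the shared slope pushes the genotypes apart. The covariate also moved the difference in internode 1 to 1128. For the 45 results on named genes, 284 of the values under other settings kept their side of the threshold, 24 passed it and 44 lost it; with 1 branch or tree left out 229 kept it, 14 passed and 97 lost it. In simulation the genotype test, 2 trees against 2, found 5% of 2-fold changes, and no setting varied depth. The gene list tests could not be run, since no identifier could be matched to a description.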

Other observations

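Chosen only after the result was seen were the tests of the mean contrast, of its overlap with the internode change, of the places of genes, and of internode 1 and the internode change for the chromosome 8 genes; those of unique reads and of the stage covariate for these genes were set before their values were seen.

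Averaged over both genotypes, the upper and lower sides of internode 2 differed in 1879 of 19610 genes. Of these, 1345 were higher and 534 lower on the upper side (edgeR, Benjamini-Hochberg). An effect of library order shared by both genotypes cannot be told apart from side in this mean. Prupe.6G129600 (chromosome 6, 10060917 to 10061642) was higher on the upper side in 8 of 8 branches, at 17.8 ± 8.87 against 4.94 ± 3.15 CPM in standard and 15.9 ± 6.51 against 2.23 ± 0.73 CPM in weeping, a mean log2 change of 2.33 (SE 0.19, edgeR adjusted p = 0.0017). Prupe.4G026300 (chromosome 4, 1228553 to 1233073) changed by 2.73 (SE 0.30, edgeR adjusted p = 0.00228). Prupe.8G018700 (chromosome 8, 1743299 to 1745197) changed by -1.18 (SE 0.26, edgeR adjusted p = 0.0256) and Prupe.4G187100 (chromosome 4, 11138518 to 11140641) by -1.17 (SE 0.24, edgeR adjusted p = 0.0183), each lower in 8 of 8 branches; without any 1 of 3 branches each lost its call, with edgeR adjusted p of 0.0504 to 0.0745. The count was 286 without the branch as a block, and 1166, 1204, 1210 and 1187 without standard replicates 2, 3 and 4 and weeping replicate 1. In internode 1 the mean contrast had 0 genes by edgeR, with 942 at an unadjusted p under 0.05 and 18 by DESeq2.

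Genes higher on the upper side of internode 2 were often also higher in internode 2 than in internode 1. Of the 1345, 573 were called higher in internode 2 over both genotypes, where independent lists would share 242.4, and 83 were called lower (223.3). Of the 534 lower genes 94 were also lower in internode 2 (88.7) and 132 higher (96.2). Both contrasts rest on the same internode 2 libraries, whose sides are summed in the internode test. The lists are therefore not independent, and what they would share without any link was not computed.

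Of the 36 genes over 2 log2 units higher on the upper side in weeping internode 2 and lower there in standard, 16 lay in a run on chromosome 8. The run spanned 212 kb, 11272704 to 11485084. Just before it, at 11258287 to 11265989, lay 2 genes almost unread in weeping trees (log2 fold changes -8.68 and -8.27). Tested genes of the run were short, with a median length of 857.5 bp against 2626 bp for all genes. Whether either bears on the run was not tested. A lower limit of 1.5 log2 units had been looked at first and gave 47 genes, the same 16 in the run, and permutation p = 0.006 for their places; with 2 units 22 of the 36 had another within 1 Mb, against a mean of 11.2 over 10000 random lists (permutation p = 0.002). All 28 tested genes of the run were lower on the upper side in standard (median log2 -1.01, 9 with an unadjusted p under 0.05) and 27 were higher in weeping (median 2.53). These medians are of edgeR's fitted changes. Medians per branch, of differences in log2(CPM + 0.5), were -1.06 to -0.39 in standard and 0.41 to 3.05 in weeping, the lowest in replicate 3. EdgeR called the difference between genotypes for 0 of the 28, with 23 at an unadjusted p under 0.05 and 20 called by DESeq2.

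Reads shared between copies do not account for the run, as 16 of its 16 weeping calls were called again on unique reads. Stage along the internode axis is made less likely but is not excluded. In weeping the run changed by 0.03 ± 0.47 log2 units from internode 1 to internode 2 (branch medians, SD, n = 4). Between the sides of internode 2 it changed by 2.12 ± 1.19. The genes were picked for the size of that side change, which favours this outcome. Weeping replicate 3 alone went the other way, with 0.64 between internodes and 0.41 between sides. That 15 of 16 were called again with the score as a covariate is no test of stage. The sides there differed in score by -0.11 to 0.08 only. One hypothesis is a difference between the genotypes in how this run of genes is read across the shoot, which may hold in internode 2. In internode 1 the branch medians averaged 0.26 ± 0.81 in weeping and -0.32 ± 0.36 in standard (SD, n = 4), a gap of 0.58 with overlapping branches, which leaves open whether it holds there. The run was picked for the pattern it shows, so its signs in internode 2 are no independent evidence, and no gene of it was named for want of descriptions.

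The 35 genes that differed between genotypes lay closer together than random lists. Of the 35, 25 had another within 1 Mb, against a mean of 10.6 and a 95th percentile of 16 over 10000 draws (permutation p = 0.0002). Of the 28 genes called in the fit on unique reads, 18 had another of that list within 1 Mb, against a mean of 6.9 (permutation p = 0.0007). Technical readings of these places had been tested before the run on chromosome 8 was taken up in their stead. On unique reads 28 genes were called, against 35 on all reads. The 9 genes higher in weeping are not what reads that fail to map in weeping trees would give. For the 26 lower genes that reading was left open.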
